A study of Homo sapiens with 4 samples.

How the data were processed

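The study measured poly(A) RNA in 4 libraries of K562 cells: 2 controls and 2 with a DHX29 knockout, as grouped by the genotype given for each sample. Per the labels' protocols, poly(A) RNA was selected from total RNA, directional libraries were prepared with a kit that keeps strand information, and sequencing was done on a NextSeq 500. The deposited values are raw read counts per gene, whole numbers that the authors did not normalize, as the values themselves show. Per the submitters' processing notes, the tools were Trim Galore 0.6.10, HISAT2 2.2.1 and featureCounts of Subread 2.0.1, with the hg38 build. The strand setting, the treatment of reads that map to several places and the annotation release used for counting are not given in the sources used here. Each column was matched to a sample by the alignment file named in the sample's description.

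The table holds 66023 entries, of which 27206 had no count in any library. Entry identifiers were matched without their version to GENCODE release 29 (GRCh38), and 56927 matched. The 9155 entries set apart as not on its primary chromosomes include every entry without a match, whose position is unknown. These 9155 entries took 7.26%, 7.28%, 7.07% and 7.01% of the counts in control replicates 1 and 2 and DHX29-KO replicates 1 and 2. Pseudogenes took 8.50%, 8.51%, 8.49% and 8.52%. Near-identical genes had nearly equal counts, so a read may have been counted at more than 1 entry, and the count of called entries includes such copies. Several named genes overlap genes annotated on the opposite strand, and without a stated strand setting reads of the partners cannot be told apart. Because of the copies, counts are also given for protein-coding genes of the primary chromosomes.

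Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with the group, glmQLFit and glmQLFTest with the group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test kept 23413 entries. The fit had 2 residual degrees of freedom per gene and a prior of 6.65, and the common biological coefficient of variation was 4.32%. Values in CPM are counts per 1000000 counts of the library, scaled by TMM factors of 0.992, 0.988, 1.01 and 1.01 in the same library order. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. The total counts of 57186656 to 65996431 per library leave mainly entries of few counts imprecise. The median chi-square statistic between replicates, over genes with a mean count above 50, was 2.10 times (controls) and 1.84 times (DHX29-KO) the value for sampling noise alone, so no libraries were merged.

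The 24 gene lists were fixed before the data were examined, as were the grouping, the tests and most alternatives. The ZNF genes and replication-dependent histones were defined by symbol pattern and the others written out by symbol. Symbols were matched through the current names, the symbols of the table and RefSeq synonyms. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. The preset takes genes as nearly independent. The estimated correlations ran from -0.043 (p53 target genes) to 0.995 (mitochondrially encoded mRNAs), with 0.734 for ribosomal proteins. With an estimated correlation camera rests on the 2 residual degrees of freedom and has little power. A threshold missed there does not show that a list is unchanged. GC3 was taken from the longest annotated coding sequence of each gene, for 98.7% of the tested protein-coding genes.

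Genes were named by a rule fixed in advance. It took DHX29; then, among genes past the threshold with both DHX29-KO libraries on the same side of both controls, a mean of at least 5 CPM and a symbol that is not a clone, LOC, LINC, antisense or pseudogene name, the 8 highest and 8 lowest log2 fold changes and the 5 smallest p in each direction; and up to 4 members with the smallest p from each list. This gave 111 genes, not all of which are reported here. Other members of the lists that are named, such as RHAG, TFRC, TAL1, BNIP3L, CHAC1, ATF4, ASNS, PPP1R15A, NDRG1, CD33, CEBPA, HBQ1 and HBD, were chosen after their values were seen, because of their function or because they went against their list.

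The steps were tested on simulated counts drawn from the real means and library sizes, 23048 entries in the simulated comparison of DHX29-KO with control. The changed genes were drawn from entries with a mean count above 50, so recovery among entries of few counts was not measured. Simulated genes varied independently of each other. Of 50 genes changed at each size, 30 were recovered at 1.3-fold, 41 at 1.5-fold, 49 at 2-fold and 50 at 4-fold. There were 13 calls among 22805 unchanged entries. The erythroid list, shifted down as a whole by 0.5 on the log2 scale, was found by camera at the preset correlation. Camera also called 3 lists that had not been shifted as a whole. A GC3 slope of 0.5 was recovered as 0.510. In the data the erythroid median was -0.15 and the difference in GC3 slope between the groups -0.0797. A list shift or slope of that size was not tried.

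The slope test for a handling difference shared with the control replicates was added after its rho was seen. Its bound, a slope more than 2 standard errors above 0.5, was passed; a bound of 1, tried after the slope of 0.568 was known, was not passed and was withdrawn because it had been picked with the slope in view.

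Alternatives were RLE and upper-quartile factors, library totals alone, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, offsets that remove a per-library trend on transcript GC content (with and without the block), each library left out in turn, a stricter threshold of 0.01 and a 2-fold limit. For the GC3 trend, ZNF genes were left out and a mean of 10 CPM was required. A fit of protein-coding genes of the primary chromosomes alone, offsets on transcript length, and GC3 of the APPRIS principal coding sequence were added after seeing the data.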

Results

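Poly(A)-selected RNA was sequenced from K562 cells, a human erythroleukaemia line that makes embryonic and fetal globins. The cells were either controls or carried a knockout of DHX29, a DExH-box helicase that binds the small ribosomal subunit and takes part in translation initiation. Each group had 2 libraries. The deposited gene counts summed to 64097391 and 64706458 in control replicates 1 and 2 and to 57186656 and 65996431 in DHX29-KO replicates 1 and 2. The labels do not say whether the replicates were separate cultures or clones. The edgeR p-values therefore measure only the spread between these samples, which may be technical. Those of camera at the preset correlation rest on the spread across genes, taken as nearly independent. If the groups came from different clones, a difference between clones could not be told apart from the knockout. For most genes replicates lay close together. The comparison covered 11459 protein-coding genes with a mean count above 50 and an unshared symbol. The median absolute log2 ratio was 0.05 between the controls and 0.05 between the DHX29-KO libraries, against 0.15 to 0.18 between groups. The SD of the log2 ratio was 0.118 between the controls and 0.230 between the DHX29-KO libraries, against 0.313 to 0.361 between groups.

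The targeted gene was examined first. DHX29 (GRCh38 chromosome 5, positions 55256245 to 55307722, minus strand) fell from 74.0 ± 1.20 CPM (TMM-scaled counts per 1000000, SD, n = 2) in the controls to 37.8 ± 1.57 in the DHX29-KO libraries. The log2 fold change was -0.97 ± 0.04 (SE), with an adjusted p of 2.4e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The value was 73.1 and 74.9 CPM in the control libraries and 36.7 and 38.9 CPM in the DHX29-KO libraries. Among the 5 tested protein-coding genes that start within 500 kb of the start of DHX29, CCNO was the one past the threshold (log2 fold change 0.25, edgeR adjusted p = 0.034). Reads from edited transcripts are still counted, so the remaining level says nothing about the protein.

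The next comparison asked which transcripts differed between DHX29-KO and control cells. Transcripts of hemoglobin chains were among those that fell, and those of SP6, S1PR1 and TP53INP1 among those that rose. Of 23413 entries tested, 4412 were higher and 4423 lower in DHX29-KO cells at an edgeR adjusted p under 0.05. Most changes were small: the median absolute log2 fold change of the called entries was 0.29. Among 13248 protein-coding genes of the primary chromosomes, 3123 were higher and 3326 lower, and at least 2-fold changes numbered 188 higher and 49 lower. Without control replicate 2 the counts over all entries were 2893 higher and 2847 lower. The 188 genes became 124 without control replicate 2, 392 without DHX29-KO replicate 2, 86 with a filter at a mean of 1 CPM and 88 with DESeq2, and the 49 became 25 and 27 under the last pair of settings.

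The genes with the highest log2 fold changes under the naming rule were SP6, S1PR1, TP53INP1, ABCA1, IKZF2, CD84, CD48 and PLEKHH2. SP6, a zinc finger transcription factor of the Sp/KLF family, rose from 1.25 ± 0.172 to 10.3 ± 0.107 CPM (SD, n = 2, log2 fold change 3.04 ± 0.10, SE, edgeR adjusted p = 6.8e-07). S1PR1, a receptor for sphingosine 1-phosphate, rose from 3.51 ± 0.296 to 16.3 ± 0.224 CPM. TP53INP1, a stress-inducible gene of the p53 pathway, rose from 12.6 ± 0.146 to 46.5 ± 1.32 CPM (log2 fold change 1.89 ± 0.05, edgeR adjusted p = 1.3e-07), and it overlaps NDUFAF6 on the opposite strand. The cholesterol efflux transporter ABCA1 rose by 1.85 and IKZF2, an Ikaros-family transcription factor of lymphoid cells, by 1.74 on the log2 scale. CD84 and CD48, immune receptors of the SLAM family that lie close together on chromosome 1, rose by 1.68 and 1.54. PLEKHH2 rose from 6.49 ± 0.427 to 18.4 ± 1.32 CPM. TSC22D1 (log2 fold change 1.04) was added by its small p.

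Of the 8 lowest genes, 5 encode hemoglobin chains. HBZ, the embryonic zeta chain, fell from 229.4 ± 3.77 to 64.2 ± 2.14 CPM (SD, n = 2, log2 fold change -1.84 ± 0.04, SE, edgeR adjusted p = 5.7e-08), and HBM from 291.8 ± 1.31 to 80.6 ± 3.79 CPM. The fetal gamma chain genes HBG2 and HBG1 fell from 1487 ± 44.6 to 524.1 ± 0.164 CPM and from 1036 ± 42.7 to 371.0 ± 1.90 CPM. HBA1 and HBA2, which encode the same alpha chain, each had a log2 fold change of -1.22. HBQ1 fell less (log2 fold change -0.38, edgeR adjusted p = 0.0024), HBD did not pass (-0.18, 0.47), and HBB had no count. HBE1, the embryonic epsilon chain, had a log2 fold change of -4.11 ± 0.65 (edgeR adjusted p = 0.0014), but its counts were 4608 and 6092 in the controls and 589 and 3 in DHX29-KO replicates 1 and 2. Without DHX29-KO replicate 1 the value was -10.80, and DESeq2 gave an adjusted p of 0.17. ARRDC4 and TXNIP, arrestin-family genes that restrain glucose uptake, had log2 fold changes of -2.04 and -1.58, and KLF10, a TGF-beta-inducible transcription factor, of -1.33. HBZ and HBM overlap on the same strand, as do HBG2 and HBE1, and the near-identical pairs HBA1 and HBA2, HBG1 and HBG2 can share reads, so the split within each pair is uncertain.

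**Figure D1:**
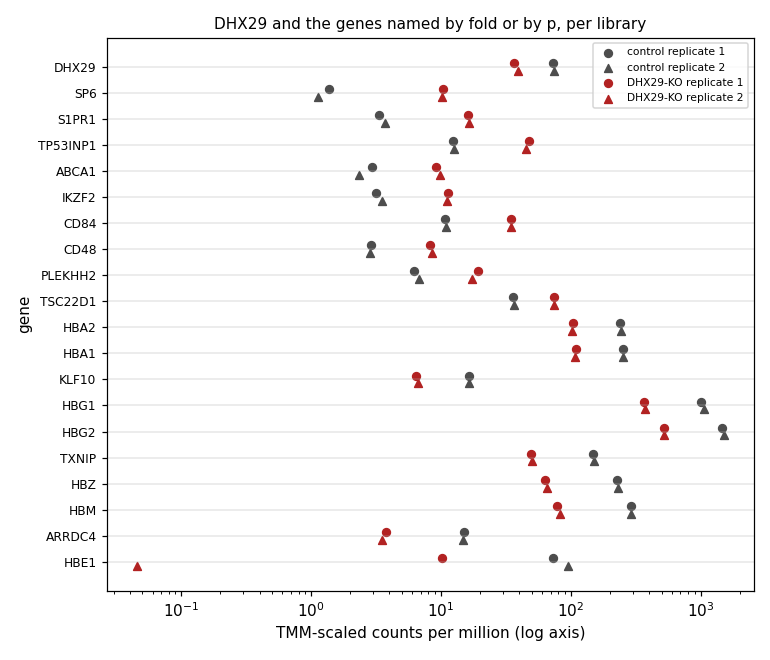
TMM-scaled CPM (log axis) of DHX29 and of the 19 genes named by fold change or by p, in each of the 4 libraries (grey, control; red, DHX29-KO; circles, replicate 1; triangles, replicate 2). The 2 libraries of a group lie close together for each gene except HBE1, at 10.2 and 0.0452 CPM in the DHX29-KO libraries.

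Erythroid genes were then taken as a fixed list. Of 43 tested, 23 fell, 5 rose and 15 did not pass the threshold, with a median log2 fold change of -0.15 (camera adjusted p = 2.1e-22, Down, adjusted p = 0.19 with an estimated correlation). Beside the globins, the log2 fold change was -0.97 for RHAG (a red cell membrane glycoprotein) and -0.35 for TFRC (the transferrin receptor). TAL1 and BNIP3L, both with roles in erythroid maturation, rose by 0.44 and 0.34. Replication-dependent histone genes had the lowest median of the 24 lists: 31 of 50 fell, none rose and 19 did not pass, with a median of -0.70 (camera adjusted p = 8.6e-22, Down, adjusted p = 0.19 with an estimated correlation). HIST1H1C fell from 433.8 ± 20.4 to 227.1 ± 1.81 CPM (SD, n = 2) and HIST1H2AC from 223.7 ± 9.05 to 129.4 ± 1.13 CPM. HIST2H2AA3 and HIST2H2AA4, neighbouring copies with nearly equal counts in each library, had log2 fold changes of -0.81 and -0.82. Most mRNAs of this class lack a poly(A) tail, so a poly(A)-selected library reads only part of them.

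Most genes in each of 3 stress response lists were lower. Of 30 genes of the integrated stress response, the programme run by ATF4, 26 fell, 1 rose and 3 did not pass (median -0.33, camera adjusted p = 2.5e-27, Down, adjusted p = 0.19 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, fell from 139.2 ± 1.40 to 73.3 ± 1.99 CPM (SD, n = 2, log2 fold change -0.92 ± 0.03, SE, edgeR adjusted p = 1.2e-06). The log2 fold change was -0.95 for CHAC1, -0.87 for DDIT4, whose product inhibits mTORC1, -0.64 for the amino acid transporter SLC7A5, -0.45 for asparagine synthetase, ASNS, and -0.36 for ATF4 itself. PPP1R15A rose by 0.16. Of 20 genes of the unfolded protein response of the endoplasmic reticulum, 13 fell, 1 rose and 6 did not pass (median -0.22, camera adjusted p = 2.8e-07, adjusted p = 0.19 with an estimated correlation), with XBP1 at -0.71 and the chaperone HSPA5 at -0.50. Of 19 cytosolic heat shock genes, 14 fell, 2 rose and 3 did not pass (median -0.27, camera adjusted p = 1.5e-07, adjusted p = 0.43 with an estimated correlation). DNAJA1 was at -0.40 and HSPA1A and HSPA1B, near-identical copies, at -0.35 and -0.33.

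Of 32 G1/S and DNA replication genes, 28 fell, none rose and 4 did not pass (median -0.28, camera adjusted p = 8.6e-22, Down, adjusted p = 0.26 with an estimated correlation). GINS2, a subunit of the replicative helicase, fell from 47.0 ± 1.14 to 29.3 ± 0.627 CPM (SD, n = 2), and RRM2, a subunit of ribonucleotide reductase, from 188.6 ± 1.31 to 130.4 ± 0.656 CPM. Of 35 G2/M genes, 15 fell, 2 rose and 18 did not pass (median -0.09, camera adjusted p = 9.5e-04, adjusted p = 0.65 with an estimated correlation). MYC, among the immediate early genes, fell from 538.9 ± 6.997 to 334.4 ± 4.79 CPM (log2 fold change -0.69, edgeR adjusted p = 7.4e-06). That list had 6 higher, 6 lower and 8 not passing of 20 (camera adjusted p = 0.997), with BTG2, an antiproliferative gene, at 0.92 and ATF3 at -0.90. Its median was -0.05 and its mean 0.07.

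Of 39 translation initiation factors, 23 fell, 1 rose and 15 did not pass (median -0.15, camera adjusted p = 4.4e-05, Down, adjusted p = 0.63 with an estimated correlation). EIF1AX, which binds the ribosomal A site during scanning, fell from 162.5 ± 3.97 to 120.2 ± 0.217 CPM (SD, n = 2), whereas EIF4G3 rose from 81.6 ± 0.539 to 109.9 ± 2.17 CPM. Of 79 cytosolic ribosomal protein genes, 53 fell, none rose and 26 did not pass (median -0.13, camera adjusted p = 2.3e-10, adjusted p = 0.63 with an estimated correlation), with RPS26 at -0.31 and RPL35 at -0.27. Of 17 other DEAH-box helicases, 7 fell, 2 rose and 8 did not pass (camera adjusted p = 0.14); the median was -0.03, the mean 0.0031, and DHX37 and DHX34 were at -0.31 and -0.30. At the preset correlation, camera called this list Down with no filter (adjusted p = 0.045) and with the trend on transcript length removed (0.0095). With an estimated correlation the main fit gave a camera adjusted p of 0.52. Of 40 mRNA decay factors, 14 rose, 6 fell and 20 did not pass (camera adjusted p = 0.15), with XRN1, the cytoplasmic 5'-to-3' exonuclease, up by 0.44 and SMG1, a kinase of nonsense-mediated decay, by 0.28. With the length trend removed, SMG1 was at 0.04 (edgeR adjusted p = 0.33).

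Metabolic genes moved in both directions. Of 24 cholesterol synthesis genes, 17 fell, none rose and 7 did not pass (median -0.28, camera adjusted p = 5.1e-10, Down, adjusted p = 0.19 with an estimated correlation), among them HMGCS1 at -0.49 and DHCR7 at -0.47. Of 26 glycolysis and hypoxia genes, 12 fell, 7 rose and 7 did not pass (median -0.15, camera adjusted p = 0.0033, adjusted p = 0.52 with an estimated correlation). The glycolytic enzymes GAPDH and ENO1 were at -0.38 and -0.39, and NDRG1, a hypoxia-inducible gene, rose by 1.20. Of 49 nuclear genes of oxidative phosphorylation, 39 fell, none rose and 10 did not pass (median -0.17, camera adjusted p = 5.1e-10, adjusted p = 0.52 with an estimated correlation). The 13 mitochondrially encoded mRNAs went the other way, with 10 higher, none lower and 3 not passing (median 0.41, camera adjusted p = 9.5e-04, Up, adjusted p = 0.65 with an estimated correlation). The share of counts from the mitochondrial genome was 4.01% and 3.03% in the control libraries and 4.70% and 4.79% in the DHX29-KO libraries. The median of this list was 0.63 without control replicate 1 and 0.21 without control replicate 2, where MT-CO2 moved from 0.53 to 0.35, and with DESeq2 the list missed the threshold (cameraPR adjusted p = 0.052).

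Markers of other blood lineages were looked at as a further check. Of 12 myeloid and monocyte markers tested, 8 rose, 2 fell and 2 did not pass (median 0.60, camera adjusted p = 1.3e-04, Up, adjusted p = 0.52 with an estimated correlation). ITGAM, the alpha M integrin, rose from 56.5 ± 2.04 to 100.8 ± 2.56 CPM (SD, n = 2), and SPI1, the PU.1 transcription factor, from 44.7 ± 0.768 to 59.7 ± 0.769 CPM, while CD33 was at -1.20 and CEBPA at -0.38 on the log2 scale. In this list the 2 DHX29-KO libraries differed by a median of -0.28 (replicate 2 over 1) and the controls by -0.0048. Without DHX29-KO replicate 1 the list kept its call (camera adjusted p = 7.2e-04, median 0.50). Of 17 NF-kB and inflammatory genes, 4 rose, none fell and 13 did not pass (camera adjusted p = 0.15). ICAM1 rose by 0.26 and TNFAIP2 by 0.28; NFKBIA (0.23) and BIRC3 (0.60) also passed but missed the threshold without DHX29-KO replicate 1 (edgeR adjusted p = 0.053 and 0.14) and without control replicate 1 (0.051 and 0.096). Without control replicate 2, BIRC3 (0.10) and TNFAIP2 (0.085) missed it as well. The median of the NF-kB list was 0.28; it was -0.14 without DHX29-KO replicate 1 (camera adjusted p = 0.45, Down) and 1.31 without DHX29-KO replicate 2 (camera adjusted p = 5.5e-20, Up). With no filter on low counts the camera adjusted p was 0.025 (Up).

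DHX29-KO replicate 1 had some transcripts at a higher level than its partner. In that library 22 protein-coding genes reached at least 2 CPM and at least 5 times the level of DHX29-KO replicate 2, against 0 genes in the opposite direction and 1 in each direction between the controls. SERPINB2, an inhibitor of plasminogen activators, had counts of 96, 32, 1291 and 9 in control replicates 1 and 2 and DHX29-KO replicates 1 and 2, and the chemokine CXCL8 had 46, 23, 551 and 2. IL1B was at 7.73 CPM in DHX29-KO replicate 1 and 0.0603 CPM in replicate 2, and CD44 at 5.36 and 0.0301 CPM. Of the 22 genes, 19 stayed under 1 CPM in the other 3 libraries, 5 belonged to the NF-kB list and 0 to the myeloid list. In the group comparison 3 of the 22 passed the threshold, among them NCF1 and HBE1; these genes were chosen after their values were seen.

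**Figure D2:**
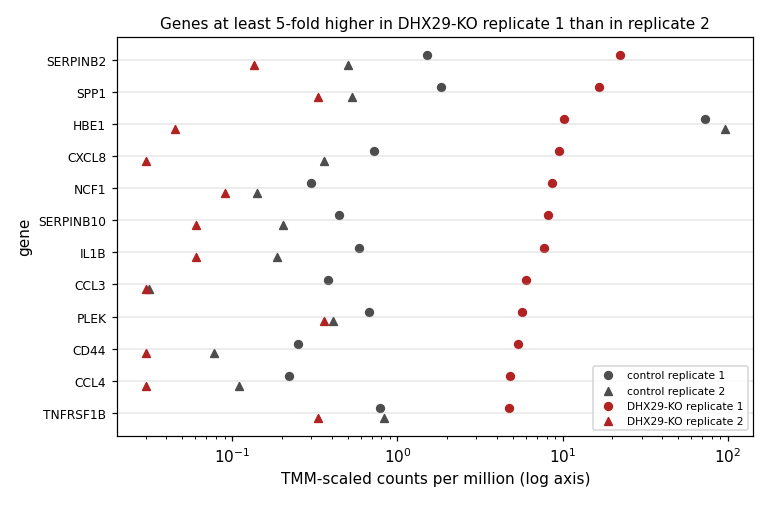
TMM-scaled CPM (log axis) of the 12 genes with the highest level in DHX29-KO replicate 1 among the 22 that were at least 5-fold higher there than in replicate 2 (grey, control; red, DHX29-KO; circles, replicate 1; triangles, replicate 2). SERPINB2 stands at 22.3 CPM in that library and 0.136 CPM in its partner, and HBE1 is the gene with higher values in both controls.

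The remaining lists had no camera call. Of 23 type I interferon-stimulated genes, 8 rose, 4 fell and 11 did not pass (camera adjusted p = 0.34), with RSAD2, an antiviral enzyme, at 1.09 and SAMD9 at -0.93. Of 11 megakaryocyte and platelet genes, 3 rose, 2 fell and 6 did not pass (camera adjusted p = 0.67), with MEIS1 at 0.39 and RUNX1 at -0.26; without DHX29-KO replicate 2 the camera adjusted p was 0.039 (Up). Of 17 p53 target genes, 5 rose, 5 fell and 7 did not pass (camera adjusted p = 0.47, median -0.02, mean 0.10), with SESN1 at 0.40 and AEN at -0.63. Of 419 ZNF genes, 79 rose, 74 fell and 266 did not pass (camera adjusted p = 0.51), with ZNF431 at 0.69. Lymphoid markers had 1 of 6 tested higher (CD7, 0.38, camera adjusted p = 0.59), and epithelial and fibroblast markers 1 higher and 3 lower of 7 (TAGLN, 0.70, and KRT8, -0.27, camera adjusted p = 0.51). Counts adjusted over the list alone were close to those over all genes: 59 lower ribosomal protein genes, 33 lower histone genes, 27 lower integrated stress response genes and 20 lower cholesterol synthesis genes. Of the 24 lists tested, 14 were called by camera with its preset correlation and none with an estimated correlation (smallest adjusted p = 0.19). The latter setting rests on 2 residual degrees of freedom and has little power. Fry, which asks whether the members of a list move on balance in 1 direction, called 11. These included the ZNF genes (fry adjusted p = 0.018) and other DEAH-box helicases (0.025), which camera did not call. They did not include the initiation factors (0.064), ribosomal proteins (0.063), G2/M genes (0.10), myeloid markers (0.064) or mitochondrially encoded mRNAs (0.23).

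**Figure D3:**
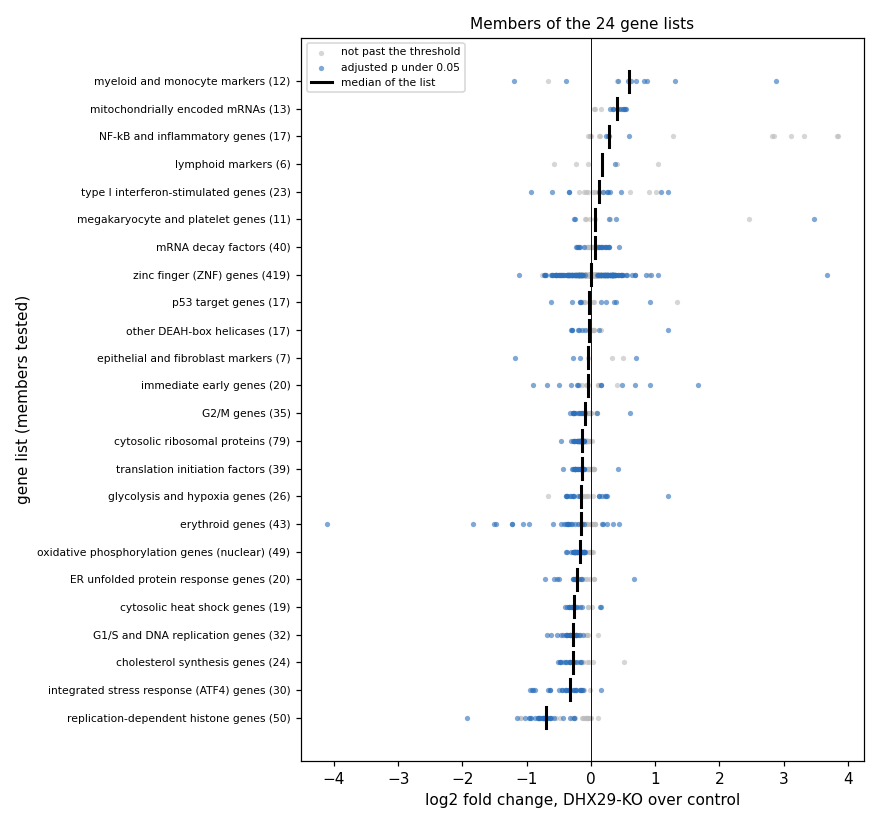
Log2 fold change (DHX29-KO over control) of each tested member of the 24 gene lists, with blue points past an edgeR adjusted p of 0.05, grey points not past it, and a black bar at the median of each list. The medians run from -0.70 for the replication-dependent histone genes to 0.60 for the myeloid and monocyte markers.

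The last comparison asked whether fold changes followed codon composition, since DHX29 acts on scanning and decoding ribosomes. GC3, the share of G or C at the third codon position, was known for 13072 protein-coding genes. Across these genes, which are not independent replicates, the log2 fold change had a Spearman rho of -0.0640 with GC3. Over 11644 genes the same rho was -0.0817 for the ratio of control replicate 2 to 1 and -0.0611 for DHX29-KO replicate 2 to 1, with a sign set by the order of the replicates, and -0.111 to -0.0489 for the 4 ratios of a DHX29-KO to a control library. Median log2 fold changes ran from 0.04 in the decile of lowest GC3 to -0.04 in the highest. Per library, the slope on GC3 was fitted to log2 CPM minus the gene's mean over all libraries. The 2 group means therefore mirror each other by construction. They were 0.0398 ± 0.0235 (SD, n = 2) in controls and -0.0398 ± 0.0553 in DHX29-KO libraries. Only the difference, -0.0797 for DHX29-KO minus control, carries information. Its two-sided exact permutation p was 0.333, the smallest that 2 libraries against 2 can give. The group trend was -0.0379 without control replicate 1, -0.0672 without control replicate 2, -0.0865 without DHX29-KO replicate 1 and -0.0410 without DHX29-KO replicate 2. It was -0.113 at a mean of at least 10 CPM, -0.0381 without a filter, 0.000781 with GC offsets and, in a fit added after seeing the data, -0.0235 with length offsets.

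**Figure D4:**
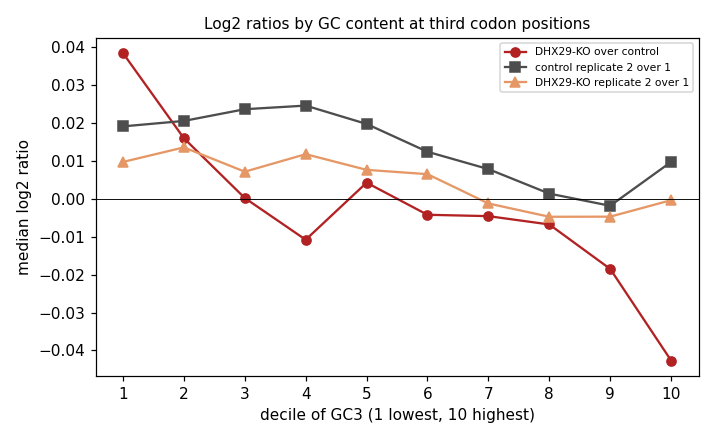
Median log2 ratio (vertical axis) of the genes in each of 10 deciles of GC3 (horizontal axis), for DHX29-KO over control (red) and for the ratios between replicates of each group (grey and orange). The group medians run from 0.04 to -0.04, and all medians lie within that range.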

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

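Length offsets, a fit of protein-coding genes alone and APPRIS coding sequences were chosen after the data were seen; the other settings were fixed before. The DHX29 log2 fold change kept its direction and call in every setting run (-1.03 to -0.93). The counts of higher and lower entries stayed within 1.5 times 4412 and 4423 except in these settings: DESeq2 called 2839 higher, a threshold of 0.01 left 2742 higher and 2821 lower, a 2-fold limit 359 higher and 105 lower, and the fit without control replicate 2 gave 2893 and 2847. Leaving out each library gave up to 3563 higher and 4046 lower. Fewer samples lower the power of these fits, in which the lone library of a group is assumed to vary like the others. Protein-coding genes at least 2-fold higher numbered 86 and lower 25 with a filter at a mean of 1 CPM, which removes low genes, and 88 and 27 with DESeq2; leaving out each library gave 124 to 392 higher. The cause of the other shifts was not tested.

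The number of called gene lists was 13 to 16 in the settings run with the preset correlation and 0 with an estimated correlation. Of 383 values of single lists under other settings with the preset correlation, 375 kept their side of the threshold; 7 gained a call and 1 (mitochondrially encoded mRNAs with DESeq2) lost it. No called list and no named gene past the threshold changed direction. Of 1750 values of the 110 named genes other than DHX29, 1728 kept their side of the threshold, 19 lost it and 3 gained it; 13 of the losses came from leaving out a library. The GC3 rho of -0.0640 was -0.0381 without a filter, 0.000781 with GC offsets, 0.000761 with GC offsets and the replicate block, -0.0235 with length offsets and -0.113 at a mean of at least 10 CPM. Leaving out each library gave -0.0865 to -0.0379. GC offsets remove much of any such trend by construction; the cause of the other shifts was not tested. The GC3 of MANE or Ensembl canonical transcripts was not run, because the annotation used carries neither tag.

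Groups share the numbers 1 and 2, which the labels do not tie to a shared culture or day. Deviations from the group means correlated at 0.163 between same-numbered libraries, and with 2 pairs the numbers do not establish a pairing. With the replicate block 4638 entries were higher and 4676 lower, DHX29 was at -0.97, 15 lists were called, and the GC3 rho was -0.0638. The list gained was that of NF-kB and inflammatory genes (camera adjusted p = 0.042, and 0.022 with GC offsets and the block). Depth limits the genes of few counts: F2RL2 had 1, 2, 13 and 22 counts and COL1A1 26, 28, 11 and 12, and DESeq2 gave neither an adjusted p.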

Other observations

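All tests in this part were chosen after the data were seen. For the removal of the length trend from the gene lists, the bounds were set before that result was seen.

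Lower globin transcripts were weighed first. A loss of gene copies that reached beyond the clusters would lower their neighbours. Pooled over both clusters, 49 expressed genes within 1 Mb had a median log2 fold change of -0.0230 (range -0.585 to 0.496). Most of these genes lay near the alpha cluster. The median argues against such a wide loss. A loss confined to the globin genes would leave the neighbours level, so these values cannot test it. A shift of reads between paralogs would leave the sum of each cluster level. The summed globin genes and pseudogenes of the alpha cluster (HBZ, HBM, HBZP1, HBA2, HBA1 and HBQ1) were at 1183 and 1191 CPM in controls and 405.2 and 414.7 CPM in DHX29-KO libraries, and even the highest DHX29-KO over the lowest control sum gave a log2 ratio of -1.49 in the cluster nearer 0 (HBB, HBD, HBBP1, HBG1, HBG2 and HBE1 of the beta cluster), which argues against that too. A lower erythroid programme may take part: the 35 erythroid genes other than globins had a median of -0.11, with 16 lower and 5 higher. Camera's p in edgeR's fit passed at the preset correlation, which takes genes as nearly independent. It did not pass with an estimated correlation, which rests on 2 residual degrees of freedom. Neither setting decides, so this stays open.

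The inflammatory transcripts of DHX29-KO replicate 1 were weighed next. Leukocytes that express HLA class II genes could bring such transcripts, but the summed CPM of CD74, HLA-DRA and HLA-DRB1 differed by 0.0131 between the DHX29-KO libraries, with no HLA-DRA count in any library, far below the 22.3 CPM of SERPINB2. Other leukocyte transcripts were higher in that library: HLA-B (class I), S100A9, S100A8 and PTPRC were at 1.22, 1.93, 0.362 and 1.79 CPM there and at most at 0.0472, 0.0469, 0.00 and 0.874 CPM in the other 3 libraries. Of the raised genes 19 stayed under 1 CPM in the other 3 libraries, and a table of summed counts does not say whether a subset of the cultured cells or RNA of other cells without class II genes is the source, so these cannot be told apart. Leaving out HBE1, the counts of 21 of these genes in control replicate 1 were a median of 8.33% of those in DHX29-KO replicate 1 (range 3.81% to 26.1%), against 3.33% in control replicate 2 and 1.06% in DHX29-KO replicate 2.

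Fold changes rose with transcript length, with a Spearman rho of 0.268 across 13072 genes, which are not independent replicates. The rho of the log2 ratio with length was 0.273 to 0.338 between libraries of different groups, -0.182 between the controls and 0.0769 between the DHX29-KO libraries; the smallest of the former was 1.505 times the largest of the latter in size, which does not settle whether the trend follows the groups. The ratio of control replicate 1 to 2 correlated across genes with the group difference at a rho of 0.236 and a slope of 0.568 (standard error 0.0236), and that of DHX29-KO replicate 1 to 2 at 0.115 and 0.167. The controls are in both quantities, which alone can give a slope up to 0.5, and the standard error takes genes as independent. The genes raised in DHX29-KO replicate 1 were not left out of this fit. Most of them were also higher in control replicate 1 than in control replicate 2, which can raise the slope. A handling difference that also separates the controls may contribute, but the small margin over 0.5 does not decide it. Of the 14 lists called at camera's preset correlation, 14 stayed called in their direction with the trend removed. The rho with length was then 0.0587. This argues against the length trend as the whole cause of these calls. With an estimated correlation, camera called no list in the main fit. The effect of the DHX29 knockout on long transcripts stays among the open explanations, as untested.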
